A study of Mus musculus with 9 samples.

How the data were processed

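Gene expression was measured on 9 microarrays, 1 for each of 9 mice. Per the labels, the mice were 8.5 months old and carried the 5XFAD model of Alzheimer's disease, mouse TREM2 was absent, and each mouse expressed the common variant of human TREM2, its R47H variant or no human TREM2. Per the labels' protocols, brains were taken after perfusion with saline, dissociated with a commercial kit, and sorted by flow cytometry for CD45+ CD11b+ cells, which are called microglia. Cells were sorted into lysis buffer, RNA was purified on small columns, and biotin-labelled material was prepared from 2 ng of total RNA. Each of the 3 genotypes had 3 mice, 1 female and 2 males, and the labels name each as a separate mouse.

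The deposited table held 1 log2 value per probe set and array for 35556 probe sets, as read from the values themselves, which ran from 1.31 to 13.9. Array medians lay between 5.28 and 5.35. The background correction, the normalization between arrays and the method that joined probes into probe sets are not given in the sources used here. The values were used as deposited, and the scale was taken as log2 from their range. The comment line of the probe annotation identifies the platform as an Affymetrix Gene ST array. No scanner files, scan dates or batches were used here. Correlations between arrays were 0.981 to 0.990 over all probe sets, and the SD of the differences between any 2 arrays was 0.32 to 0.43 on the log2 scale, so no 2 arrays held the same values.

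Probe sets were named from the platform annotation, whose date is not given in the sources used here. A single gene symbol was listed for 21789 probe sets, several symbols for 1621 and none for 12146. Of the single-symbol probe sets, 21698 matched a RefSeq gene by Entrez identifier, and 0 symbols needed an update. Only single-symbol probe sets were used for named genes. Where a gene had more than 1 probe set (999 genes) the probe set with the highest mean over all arrays stood for it. Genes whose mean over the 9 arrays was at or above the median of all probe sets (50%, a log2 value of 5.31) were tested, which left 10795 of 19938 genes. A probe set can cross-hybridise with close paralogs, and this was not checked because no probe sequences were used here.

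Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values of all 9 arrays, with a term for each genotype and one for sex, leaving 5 residual degrees of freedom to which eBayes added 3.73 prior degrees of freedom. The differences tested were CV minus KO, R47H minus KO, R47H minus CV and female minus male, plus an F-test of any genotype difference. CV, R47H and KO denote mice with the common variant, with R47H and with no human TREM2. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Standard errors (SE) of differences come from this model, and group means are given with the SD over 3 mice. Array number limits the precision: the median residual SD was 0.12 on the log2 scale. With 3 mice against 3, a permutation test cannot go below p = 0.10, so single genes rest on the limma model.

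In all, 31 lists were fixed, 20 of pathways or microglial states and 11 of markers of other cell types. They held 587 members, of which 528 had a single-symbol probe set and 445 were tested. Lists were tested with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 31 lists within each comparison. A list score per mouse was the mean over members of each gene's deviation from its mean over all arrays. Scores were compared among genotypes by an exact permutation test over 1680 arrangements of the 9 mice, whose smallest possible p is 0.00357.

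The genes named in the text followed a rule that, like the groups, models, lists and alternatives, was fixed before the data were examined. It took Trem2, Tyrobp and the genes that check sex. For each comparison it took the 10 largest positive and 10 largest negative log2 differences among called genes whose groups did not overlap, or all if fewer. It took up to 4 members of each list and comparison with the smallest p, and the R47H minus KO values of the genes named for CV minus KO. Predicted genes, olfactory receptors and unnamed probe sets were counted and left unnamed. Genes named outside this rule are identified as chosen after their values were seen.

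The model was first tested on simulated data built on the 10795 genes for CV minus KO, with 50 genes changed at each size. It recovered 58% of genes changed by 0.5 on the log2 scale, 98% at 1, 98% at 2 and 100% at 3, with 4 false calls among 181. Noise was drawn independently for each gene, with the same SD in all groups. Not all genes on these arrays follow that, so the figures may be too favourable. In that simulation R47H minus KO, where nothing had been changed, gave 0 calls. The correlation between comparisons that share the KO arrays was set against 100 simulations of unchanged groups. The position of R47H on the genes called in CV minus KO, and the overlap of calls, were set against 200 simulations each with R47H equal to KO and equal to CV, chosen after seeing the data. In these the called genes kept their fitted differences, the residuals of whole arrays were dealt out again with random signs, and genes were called anew.

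Alternatives covered a model without sex (for female minus male, a model of sex alone), the mouse number as a block in place of sex, the compared groups alone, quantile normalization, median centring, no filter on the mean, a stricter filter keeping 40% of probe sets, every probe set on its own, eBayes with trend and robust options, array weights, an adjusted p under 0.10, an absolute log2 difference of at least 1, and the removal of each array in turn. Covariates made from marker scores for neutrophils or oligodendrocytes, a fit of every probe set with trend and robust options, and the R47H share within mouse number were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.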

Results

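Expression was profiled in microglia, the resident macrophages of the brain, sorted as CD45+ CD11b+ cells from 9 mice of 8.5 months. All mice carried 5XFAD, a set of human transgenes that drives amyloid deposition, and lacked mouse TREM2, a lipid-sensing receptor of microglia that signals through the adaptor Tyrobp. In its place 3 mice expressed the common variant of human TREM2 (CV), 3 expressed R47H, a variant associated with a raised risk of Alzheimer's disease, and 3 expressed no human TREM2 (KO). Each group held 1 female, mouse 1, and 2 males, mice 2 and 3. The comparisons ask what human TREM2 changes in microglia facing amyloid, and how far R47H stands apart from the common variant.

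The mouse Trem2 probe set (10445781) read 7.16 ± 0.05 in KO, 7.28 ± 0.03 in R47H and 7.15 ± 0.09 in CV (log2, mean ± SD, n = 3). All mice lacked mouse TREM2, and it is not known here whether this probe set sees the altered part of the mouse gene or the human transgene, so it checks no genotype label. Tyrobp stood at 12.65 ± 0.08 in KO, 12.73 ± 0.06 in R47H and 12.72 ± 0.06 in CV. The sex labels were borne out by all 9 arrays: Xist, transcribed from the inactive X chromosome, lay at 9.38 to 9.79 in females and 3.57 to 3.97 in males. The Y-linked Eif2s3y lay at 2.85 to 2.98 in females and 6.84 to 8.14 in males. Y-linked Kdm5d lay at 4.31 to 4.63 in females and 6.13 to 6.51 in males, and Uty at 3.24 to 3.68 and 5.93 to 6.40.

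Microglia with the common variant of human TREM2 differed from microglia without TREM2 in 131 of 10795 genes, 103 higher and 28 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Atp6v0d2 (probe set 10511779), a subunit of the proton pump that acidifies lysosomes, was 24.0-fold higher (log2 difference 4.59 ± 0.14 SE, limma adjusted p = 2.7e-06). It lay at 4.50 ± 0.40 in KO and 9.09 ± 0.28 in CV. Gpnmb (10538187), a glycoprotein of phagocytic and lipid-laden macrophages, was higher by 4.32 ± 0.27 (adjusted p = 0.000332). Periostin (Postn) rose 6.26-fold, fibronectin (Fn1), also 1 of the monocyte markers, 4.61-fold, the aminopeptidase Anpep 4.22-fold, and the sialyltransferase St8sia6 3.93-fold. The integrin Itgax, known as CD11c, rose 3.67-fold and the lectin receptor Clec4d 3.37-fold, and the adjusted p of these genes ran from 0.000512 (Fn1) to 0.00835 (Clec4d). Vim, the intermediate filament vimentin, rose 3.64-fold (1.87 ± 0.13) and Plp2, a membrane protein, 3.54-fold (1.82 ± 0.28). The KO means of Atp6v0d2, Postn, Fn1 and Anpep lay below the array median, where arrays can compress differences. Compression was not measured here, so these folds are estimates and not lower bounds. With the neutrophil score as a covariate the difference of Plp2 was 1.08 (adjusted p = 0.0757).

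Genes lower with the common variant moved by less. Pde2a, which degrades cyclic nucleotides, fell by 1.14 on the log2 scale (SE 0.12, limma adjusted p = 0.00413), and Crybb1, a crystallin of resting microglia, fell by 1.02 (SE 0.11, adjusted p = 0.00402). Abcg3, Tmem154, Mlph, Gramd1b, Spg20, Slc39a12, Rapsn and Cd79b, a subunit of the B cell receptor, were lower by differences of -0.76 (Abcg3) to -0.64 (Rapsn), with adjusted p from 0.0036 (Tmem154) to 0.0415 (Gramd1b).

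The list of genes that disease-associated microglia (DAM) induce in a TREM2-dependent stage rose with the common variant. Of its 24 tested members 11 were called higher and 0 lower, and 15 were higher and 1 (Hif1a at -0.24) lower when adjusted over the list alone. The median difference was 0.57 and the mean 0.78 (camera adjusted p = 1.54e-16, and adjusted p = 0.0172 with an estimated correlation). Beside Gpnmb and Itgax these included lipoprotein lipase (Lpl, 1.70 ± 0.16), the lectin galectin-3 (Lgals3, 1.17 ± 0.12), Fabp5 (1.22 ± 0.15) and Ch25h (1.24 ± 0.17). The other called members, chosen after their values were seen, were Clec7a (1.09 ± 0.15), Cybb (1.35 ± 0.21), Axl (1.02 ± 0.18), Igf1 (0.69 ± 0.09) and Dkk2 (0.63 ± 0.10). The list was drawn from published mouse models, not from these mice. The lipid uptake, storage and efflux list passed the same test at adjusted p = 0.0462 (adjusted p = 0.392 with an estimated correlation). Its 4 called genes were the fatty acid carriers Fabp3 (0.90 ± 0.10) and Fabp5, Lpl and the cholesterol hydroxylase Ch25h, of which 3 also belong to the DAM list. Its mean was 0.21 and its median -0.0078, and 4 members were higher and 1, Lpcat3, lower when adjusted over the list alone. The call was lost without KO mouse 1, KO mouse 3, R47H mouse 1 or CV mouse 1 (adjusted p up to 0.207). Of the lysosome list 1 member, Atp6v0d2, was called and the list did not pass (median -0.04, mean 0.10, adjusted p = 0.382).

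Homeostatic microglial genes lay lower with the common variant, with 21 of 22 differences negative. Over all genes 1 (Crybb1) was called, and 6 were when adjusted over the list alone (median -0.18, camera adjusted p = 3.96e-08, and adjusted p = 0.392 with an estimated correlation). Siglech, a sialic acid-binding receptor of microglia, stood at -0.35 ± 0.07 (limma adjusted p = 0.0715), the fructose transporter Slc2a5 at -0.53 ± 0.13 and Golm1 at -0.26 ± 0.06. Cholesterol synthesis genes lay higher (5 of 16 adjusted over the list alone, median 0.17, camera adjusted p = 0.000308, and adjusted p = 0.529 with an estimated correlation). The sterol regulator Insig1 stood at 0.51 ± 0.10, the synthesis enzymes Msmo1 at 0.62 ± 0.13 and Cyp51 at 0.64 ± 0.15, and the transcription factor Srebf2 at 0.40 ± 0.10. No member was called over all genes, and without CV mouse 1 the list's adjusted p was 0.0555. MHC class II genes, which present antigen, were higher as a list (4 of 9 adjusted over the list alone, median 0.44, adjusted p = 0.00178, and adjusted p = 0.529 with an estimated correlation). H2-Aa stood at 0.95 ± 0.29, H2-Ab1 at 0.91 ± 0.28, Cd74 at 0.89 ± 0.28 and H2-DMa at 0.44 ± 0.11. Inflammatory cytokine and NF-kB targets were higher too (3 of 23 adjusted over the list alone, median 0.25, adjusted p = 1.18e-05, and adjusted p = 0.529 with an estimated correlation). The chemokine Cxcl16 stood at 0.58 ± 0.13, Tlr2 at 0.44 ± 0.11 and the prostaglandin synthase Ptgs2 at 0.62 ± 0.16. The inflammatory mean was 0.19, and 0.10 without KO mouse 2 (adjusted p = 0.000929). Immediate early genes, fixed as signs of the dissociation of tissue, passed at adjusted p = 0.00219 (median 0.11, adjusted p = 0.597 with an estimated correlation), with 1 of 24, Egr2 at 0.67 ± 0.15, adjusted over the list alone. They did not pass without KO mouse 1, KO mouse 2 or CV mouse 1 (adjusted p up to 0.206), and their mean of 0.12 was 0.05 without KO mouse 2 and 0.19 without KO mouse 3.

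Neutrophil markers also lay higher with the common variant by the list test at the preset correlation. All 11 tested were higher in CV than in KO (median 2.03, camera adjusted p = 3.35e-06, and adjusted p = 0.529 with an estimated correlation), 9 of them when adjusted over the list alone and 0 over all genes. The calprotectin subunit S100a8 lay at 9.98 ± 2.51 in KO, 10.34 ± 1.05 in R47H and 12.61 ± 0.34 in CV, a difference of 2.63 ± 0.80 (limma adjusted p = 0.208). The difference was 2.55 ± 0.81 for S100a9, and 2.83 ± 0.96 and 2.97 ± 1.01 for the antimicrobial genes Camp and Ngp. The mean of the list was 1.89, 1.18 without KO mouse 2 and 2.88 without KO mouse 3. Among genotypes the neutrophil score did not pass the exact permutation test (p = 0.204, adjusted p = 0.437). KO mouse 3 stood apart from the other KO mice, with a neutrophil score of 1.63 against -1.93 and -1.50. On the first principal component (35.7% of the variance) it lay at 7.25, near the CV mice at 8.57 to 17.2 and away from KO mice 1 and 2 at -12.9 and -12.6. Monocyte markers were also higher (7 of 7 positive, 4 adjusted over the list alone, median 0.70, adjusted p = 1.37e-05, and adjusted p = 0.392 with an estimated correlation), with Chil3 at 2.18 ± 0.77 and S100a6 at 1.56 ± 0.58. With the neutrophil score as a covariate the MHC class II list had a mean difference of 0.20 (adjusted p = 0.147) and the monocyte list 0.36 (adjusted p = 0.147). The mean of the inflammatory list fell from 0.19 to 0.08 (adjusted p = 0.0495), and that of the immediate early list turned to -0.02. Oligodendrocyte markers lay slightly lower in CV (9 of 9 negative, median -0.17, Mbp at -0.60 ± 0.15, 1 adjusted over the list alone, adjusted p = 0.0462, and adjusted p = 0.607 with an estimated correlation). That call was lost without KO mouse 1, KO mouse 2, R47H mouse 1, CV mouse 1 or CV mouse 3 (adjusted p up to 0.421), and the mean of -0.23 turned to 0.05 with the neutrophil score (adjusted p = 0.718). It lay at -0.11 without KO mouse 1 and at -0.40 without KO mouse 3.

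In CV minus KO 37 of the 131 genes differed by at least 1 on the log2 scale, and the groups did not overlap for 14.0% of all tested genes, where chance gives 10%. The count fell to 74 without KO mouse 1, 75 without KO mouse 2, and 59, 70 and 67 without CV mouse 1, 2 and 3. Without KO mouse 3, 101 of the 131 genes kept their calls. Among the genes taken by the naming rule 15 gained a call there and 3 lost it. Of the 27 named genes called here 18, Atp6v0d2, Gpnmb, Fn1 and Itgax among them, kept their calls without any 1 array. The model without sex called 77 genes, the compared groups alone 54, the neutrophil score 23, all among the 131, and every probe set tested on its own 18. All 131 genes kept their directions with the neutrophil score, at a median of 0.73 against 0.76 (median SE 0.141 against 0.107). Without sex or with every probe set the differences cannot change, because sex is balanced over genotypes and the probe sets are the same. Only the median SE could move there (0.138 and 0.111).

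**Figure D1:**
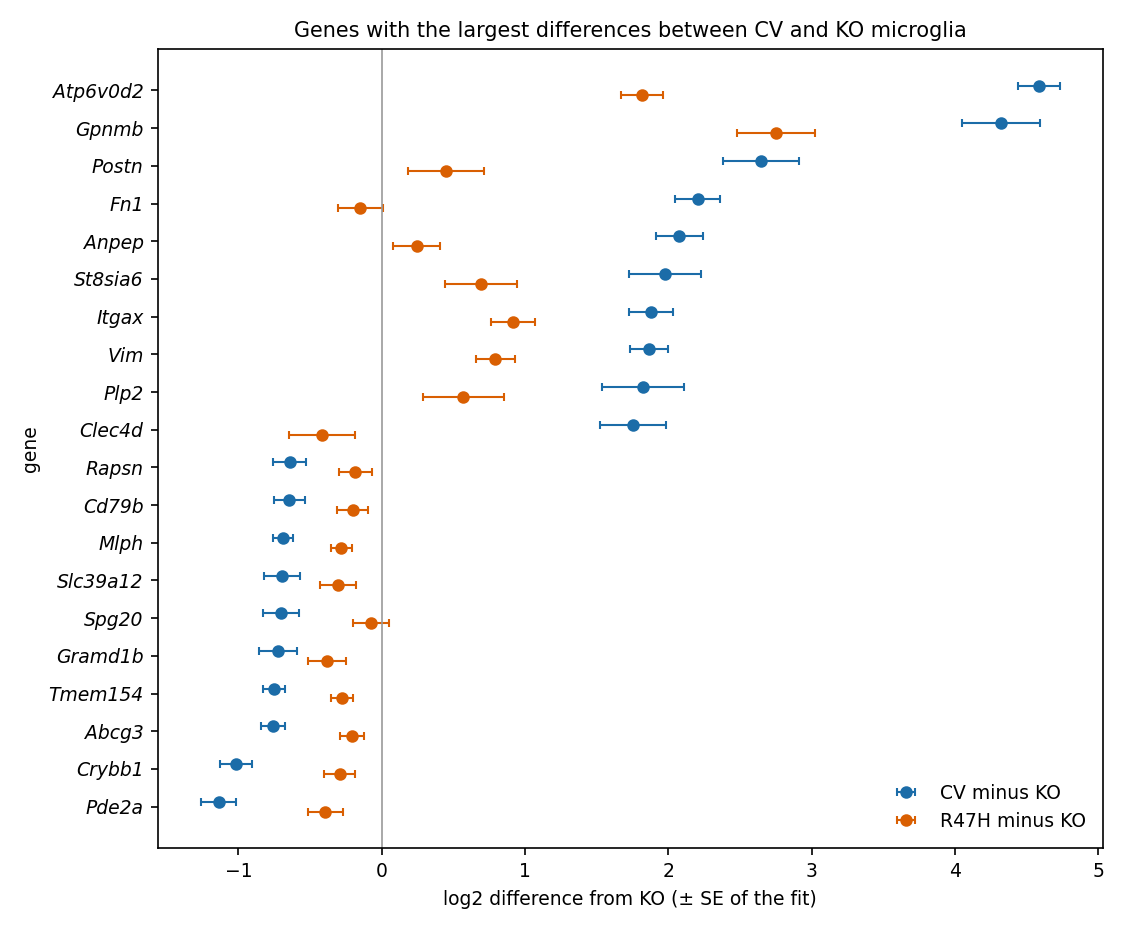
Log2 differences from KO for the 20 genes named for CV minus KO, with CV minus KO and R47H minus KO as separate points and bars of 1 SE (limma, 3 mice per group). Atp6v0d2 differed by 4.59 in CV and 1.82 in R47H, and Fn1 by 2.20 and -0.15.

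Microglia with R47H differed from those without TREM2 in 9 genes, 7 higher and 2 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Gpnmb was 6.72-fold higher (2.75 ± 0.27, limma adjusted p = 0.0143) and Atp6v0d2 3.52-fold higher (1.82 ± 0.14, adjusted p = 0.00732). The fatty acid carrier Fabp3 rose by 0.95 ± 0.10, the growth factor Igf1 by 0.84 ± 0.09 and the prion protein gene Prnp by 0.75 ± 0.07, with adjusted p of 0.0221, 0.0221 and 0.0112. Ermn, which encodes a cytoskeletal protein of oligodendrocytes, rose 3.07-fold (1.62 ± 0.19, adjusted p = 0.0221) and Sez6l2 by 1.04 ± 0.13 (adjusted p = 0.0301). Arnt, the dimer partner of hypoxia-inducible and aryl hydrocarbon receptor proteins, fell by 0.73 (SE 0.08, adjusted p = 0.0221), at 8.14 in KO, 7.41 in R47H and 8.12 in CV. The other lower gene, I830077J02Rik, chosen after its value was seen, stood at -0.77 ± 0.09 (adjusted p = 0.0301).

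The TREM2-dependent DAM list rose in R47H as well. All 24 members were positive, 2 (Gpnmb and Igf1) were called and 12 when adjusted over the list alone (median 0.41, mean 0.50, camera adjusted p = 4.92e-19, and adjusted p = 0.0124 with an estimated correlation). Lpl stood at 1.16 ± 0.16 (limma adjusted p = 0.0535) and Itgax at 0.92 ± 0.16 (adjusted p = 0.0926). Cholesterol synthesis genes lay higher (median 0.19, 0 of 16 adjusted over the list alone, adjusted p = 0.00157, and adjusted p = 0.514 with an estimated correlation), with Msmo1 at 0.47 ± 0.13. Interferon response genes were positive in 24 of 24 (median 0.28, 0 adjusted over the list alone, adjusted p = 0.000243, and adjusted p = 0.575 with an estimated correlation), with Ifit2 at 0.62 ± 0.31. This rested on R47H mouse 3, whose interferon score was 0.81 against 0.15 and -0.28 in R47H mice 1 and 2, and without it the mean difference was -0.049 (adjusted p = 0.479) against 0.28 with all mice and 0.55 without R47H mouse 2. Homeostatic genes (median -0.06, adjusted p = 0.00591), proliferation genes (median 0.09, adjusted p = 0.00591), MHC class I genes (median 0.07, adjusted p = 0.0184) and inflammatory genes (median 0.11, adjusted p = 0.0376) also passed. With an estimated correlation they had adjusted p = 0.514, 0.514, 0.514 and 0.577. Their members adjusted over the list alone numbered 0, 0, 1 (Tap1 at 0.43 ± 0.10) and 0, and Stmn1 of the proliferation list stood at 0.39 ± 0.12. The first 3 of these calls were lost without KO mouse 3 or R47H mouse 3 (adjusted p up to 0.404), and the inflammatory call without KO mouse 2, R47H mouse 3 or CV mouse 1 (up to 0.775). The inflammatory mean of 0.11 ran from 0.01 without KO mouse 2 to 0.17 without KO mouse 1, and the proliferation mean of 0.13 from 0.07 without R47H mouse 3 to 0.22 without R47H mouse 1. Over single removals the homeostatic mean of -0.08 ran from -0.10 to -0.05 and the MHC class I mean of 0.10 from 0.04 to 0.15.

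Oligodendrocyte markers moved with R47H. All 9 tested were higher than in KO, 1 (Ermn) over all genes and 8 when adjusted over the list alone (median 0.68, camera adjusted p = 1.88e-15, and adjusted p = 0.252 with an estimated correlation). The myelin genes Mobp, Mag and Cldn11 stood at 1.05 ± 0.16, 1.01 ± 0.17 and 1.42 ± 0.27 (limma adjusted p = 0.0796, 0.0926 and 0.136). Astrocyte markers were higher too (4 of 6 adjusted over the list alone, median 0.49, camera adjusted p = 0.0016, and adjusted p = 0.514 with an estimated correlation), with S100b at 1.33 ± 0.26 and Aldoc at 0.99 ± 0.23. Without the filter on the mean, 9 of 13 astrocyte markers were positive, at a median of 0.23. Neutrophil markers had a mean of -0.09 and a median of -0.23 in R47H minus KO (camera adjusted p = 0.655). With the correlation estimated over all mice, 0.82 for these markers, the camera adjusted p was 0.896. Without KO mouse 3 the mean was 0.91 (camera adjusted p = 3.05e-10 at the preset correlation). The preset correlation treats these markers as nearly independent although they move together. The last adjusted p therefore does not measure the spread between mice.

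In R47H minus KO 4 of the 9 genes differed by at least 1, and groups did not overlap for 7.11% of tested genes, below the 10% chance gives. The count was 1 without KO mouse 1, 5 without KO mouse 2, 2 without KO mouse 3 and 5 without CV mouse 3. Without R47H mouse 1, 2 and 3 it was 1, 3 and 0 (the 0 with 534 genes at an unadjusted p under 0.05, limma). Of the 8 genes named here by rule, 0 kept their calls without each array in turn, Atp6v0d2 missing only without R47H mouse 3 (1.81, adjusted p = 0.0711). With every probe set tested on its own limma called 0 (1743 at an unadjusted p under 0.05), without sex 3, with the compared groups alone 1 (Ermn), and with the neutrophil score or with trend and robust options 15 each. With the oligodendrocyte score 0 were called (limma, 446 at an unadjusted p under 0.05), and the 8 of the 9 genes tested kept their directions, at a median of 0.81 against 0.90 (SE 0.239 against 0.099), with Gpnmb at 1.48 and Sez6l2 at 0.54.

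Set directly against each other, R47H and the common variant differed in 86 genes, 41 higher and 45 lower in R47H (limma, Benjamini-Hochberg adjusted p under 0.05). Atp6v0d2 was 6.82-fold lower in R47H (-2.77 ± 0.14, adjusted p = 0.000208), Fn1 stood at -2.35 ± 0.15 (adjusted p = 0.000492), Postn at -2.20 ± 0.26, Clec4d at -2.17 ± 0.23 and Anpep at -1.83 ± 0.17. Emp1, an epithelial membrane protein, was lower by a difference of -1.73 ± 0.13 (adjusted p = 0.00129), the oxidised lipoprotein receptor Olr1 by -1.23 ± 0.12 and Gpnmb by -1.57 ± 0.27 (adjusted p = 0.0426). The ubiquitin ligase Mid1 (-2.71 ± 0.48) and the adhesion receptor Adgre5 (-1.51 ± 0.27) were lower at an adjusted p of 0.0456 each.

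Of the TREM2-dependent DAM genes 3 of 24 were lower in R47H than in CV over all genes, Gpnmb, Itgax (-0.96 ± 0.16, limma adjusted p = 0.0363) and Lgals3 (-0.72 ± 0.12, adjusted p = 0.0411). When adjusted over the list alone, 7 were lower and 1, Hif1a at 0.28, was higher (median -0.16, camera adjusted p = 0.00104, and adjusted p = 0.234 with an estimated correlation). Fabp5 stood at -0.78 ± 0.15 (adjusted p = 0.0754), Igf1 at 0.15 ± 0.09 (adjusted p = 0.564) and Fabp3 at 0.05 ± 0.10 (adjusted p = 0.88). Homeostatic genes lay higher in R47H (20 of 22 positive, median 0.11, adjusted p = 0.000101, and adjusted p = 0.395 with an estimated correlation), with Crybb1 called at 0.72 ± 0.11 (0.14 with the oligodendrocyte score), the 1 member adjusted over the list alone. Interferon genes (median 0.42, adjusted p = 8.59e-05, adjusted p = 0.656 with an estimated correlation) had Ifit2 at 0.92 ± 0.31 and 0 members adjusted over the list alone. Their mean was 0.41, 0.07 without R47H mouse 3 (adjusted p = 0.468) and 0.67 without R47H mouse 2. Of the genes named, the R47H means of Fn1 and Postn lay below the array median. Inflammatory genes (median -0.14, adjusted p = 0.003) and immediate early genes (signs of dissociation, median -0.08, adjusted p = 0.0111) lay lower in R47H. Members adjusted over the list alone numbered 0 and 1 (Egr2), and with an estimated correlation they had adjusted p = 0.645 and 0.656. The first call was lost without R47H mouse 1 (adjusted p = 0.119), the second without R47H mouse 1 (0.0669) or CV mouse 1 (0.168). The inflammatory mean of -0.09 was -0.17 without R47H mouse 3 and -0.03 without R47H mouse 1. With the neutrophil score as a covariate the inflammatory mean turned to 0.03 (adjusted p = 0.832) and the immediate early mean to 0.06 (adjusted p = 0.428).

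The genes named as higher in R47H than in CV included several known from oligodendrocytes and astrocytes. Apod, a lipid carrier, was 5.2-fold higher (2.38 ± 0.37, limma adjusted p = 0.0327). The glial calcium-binding S100b was higher by 2.12 ± 0.26 (adjusted p = 0.0127) and Cmtm5 by 1.90 ± 0.32. Sparcl1, a protein secreted by astrocytes, was higher by 1.87 ± 0.23, Ermn by 1.67 ± 0.19, and the desaturase Scd1 by 1.64 ± 0.25. The carbonic anhydrase Car2 (1.57 ± 0.25), the chaperone Cryab (1.53 ± 0.24), the myelin claudin Cldn11 (1.53 ± 0.27) and Gpm6b (1.49 ± 0.25) were called as well. With the oligodendrocyte score as a covariate the differences of Apod (-0.30), Cmtm5 (-0.14), Car2 (-0.20), Cryab (-0.15) and Gpm6b (-0.20) turned, and S100b stood at 0.72, Sparcl1 at 0.39 and Scd1 at 0.24. On the lower side Postn stood at -1.09, Clec4d at -1.21, Mid1 at -1.18 and Gpnmb at -3.19. Each of these genes had a limma adjusted p of 0.999919 in that fit, so their signs and sizes there are uncertain. The score did not overlap between R47H (0.49 to 0.81) and CV (-0.62 to -0.28), and the median SE of the called genes rose to 0.308. With the neutrophil score Apod stood at 1.46, Gpm6b at 0.96 and Mbp at 0.75. All 9 oligodendrocyte markers were higher, 5 over all genes and 9 when adjusted over the list alone (median 1.14, camera adjusted p = 8.23e-14, and adjusted p = 0.234 with an estimated correlation). Among them were Mag (1.37 ± 0.17), Mbp (1.14 ± 0.15) and Mobp (1.14 ± 0.16). Astrocyte markers had 1 call, S100b, and 4 of 6 when adjusted over the list alone (median 0.65, camera adjusted p = 3.85e-05, and adjusted p = 0.263 with an estimated correlation). Without the filter on the mean, 12 of 13 astrocyte markers were positive, at a median of 0.33. Neutrophil markers were lower in R47H (median -2.27, 10 of 11 adjusted over the list alone, 0 over all genes, adjusted p = 3.95e-07, and adjusted p = 0.395 with an estimated correlation). S100a8 stood at -2.27 ± 0.80 and Camp at -3.06 ± 0.96. Monocyte markers were lower as well (median -0.94, Fn1 called, 6 of 7 adjusted over the list alone, adjusted p = 2.9e-08, and adjusted p = 0.234 with an estimated correlation), with Chil3 at -2.75 ± 0.77. Their mean was -1.40, and -0.63 with the neutrophil score (adjusted p = 1.22e-05).

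In R47H minus CV 40 of the 86 genes differed by at least 1, and groups did not overlap for 14.9% of tested genes against 10% by chance. The count was 132 without KO mouse 3, 9, 37 and 24 without R47H mouse 1, 2 and 3, and 15, 23 and 9 without CV mouse 1, 2 and 3. Of 32 named genes called here 4 (Atp6v0d2, Fn1, Anpep and Emp1) kept their calls without any 1 array. With the neutrophil score as a covariate 9 genes were called, and the 86 genes kept their directions at a median of 0.78 against 0.92, with the median SE up from 0.125 to 0.157. With the oligodendrocyte score 0 were called (limma, 371 at an unadjusted p under 0.05), and 72 of the 81 genes tested kept their directions, at a median of 0.54 against 0.88, with the SE up from 0.1197 to 0.308. With every probe set tested on its own 5 were called, and with no filter 48.

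R47H microglia lay between the other groups for most genes that the common variant moved. For 117 of the 131 genes the R47H mean fell between the KO and CV means, for 3 it lay beyond CV and for 11 on the far side of KO. The 117 are 89.3% of the genes, against a median of 55.4% (highest 84.6%) in 200 simulations where R47H equalled KO and 54.7% (highest 77.4%) where it equalled CV. The median R47H difference was 36.3% of the CV difference, 38.1% for the 103 higher and 30.9% for the 28 lower genes. Where R47H equalled KO the simulated median was 1.84% (highest 37.0%, 1 of 200 at or above the observed share), and where it equalled CV 98.4% (lowest 69.5%). R47H minus KO stood at 0.45 for Postn, -0.15 for Fn1, 0.24 for Anpep, -0.41 for Clec4d, 0.69 for St8sia6, 0.57 for Plp2 and 0.79 for Vim. Over the DAM list, which was not selected on these mice, the R47H mice reached 64.5% of the CV difference, 67.5% among the females (1 mouse per group) and 63.4% among the males (2 per group). The DAM score was -0.43 ± 0.22 in KO, 0.08 ± 0.17 in R47H and 0.35 ± 0.13 in CV (exact permutation p = 0.00714, two-sided, adjusted p = 0.0554 over 31 lists). The homeostatic score was 0.10 ± 0.07, 0.02 ± 0.05 and -0.13 ± 0.04 (exact permutation p = 0.00714, adjusted p = 0.0554). The oligodendrocyte score was -0.21 ± 0.38, 0.64 ± 0.16 and -0.44 ± 0.17 (exact permutation p = 0.0143, adjusted p = 0.0886).

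In the F-test of any genotype difference limma called 142 of 10795 genes. That count was 78 and 91 without KO mouse 1 and 2, 75, 76 and 72 without R47H mouse 1, 2 and 3, and 35, 49 and 35 without CV mouse 1, 2 and 3. Only without KO mouse 3 did the count rise. It was 85 without sex, 37 with the neutrophil score and 17 with every probe set tested on its own. Against KO, 5 genes, Gpnmb, Atp6v0d2, Fabp3, Igf1 and Prnp, were higher in both CV and R47H, and 0 were lower in both. Simulations in which R47H equalled KO gave a median of 0 genes higher in both (highest 2), and those in which it equalled CV 77 (lowest 48). Of the 103 genes higher in CV than in KO, 36 were lower in R47H than in CV, and of the 28 lower genes 7 were higher. Simulations in which R47H equalled CV gave medians of 0 and 0 (highest 26 and 2), and those in which it equalled KO 77.5 and 17 (lowest 46 and 6). Across genes, which are not independent replicates, the differences from KO correlated at 0.346 against 0.501 in simulations without effects, with a covariance of 0.0121 against 0.00661, a difference of 0.00551. The 3 KO arrays cannot be split into parts of 2 or more, so part of any excess may come from the shared arrays.

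**Figure D2:**
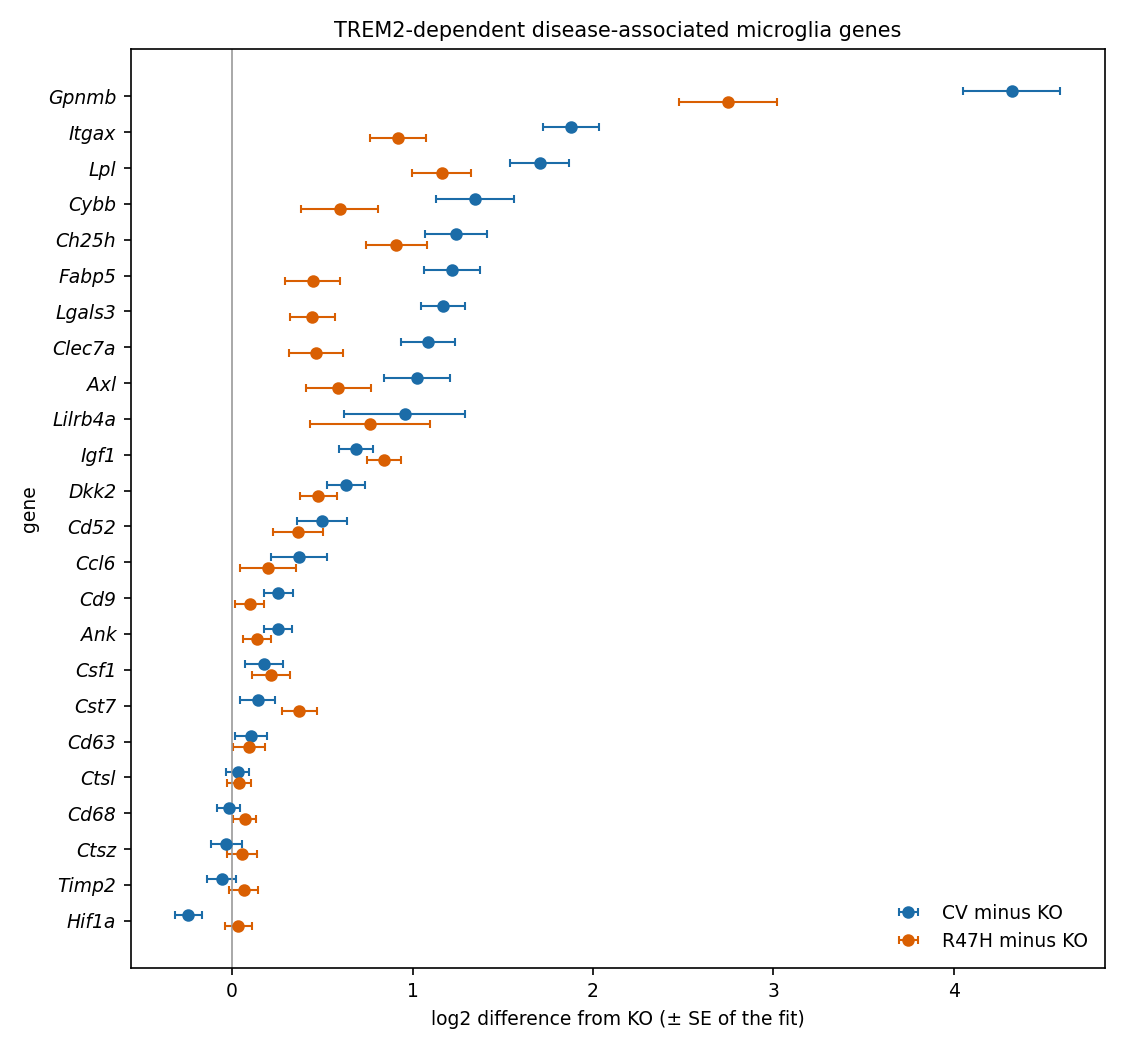
Log2 differences from KO of the 24 tested TREM2-dependent DAM genes, with CV minus KO and R47H minus KO as separate points and bars of 1 SE (limma, 3 mice per group). Of these genes 20 were positive in CV and 24 in R47H.

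**Figure D3:**
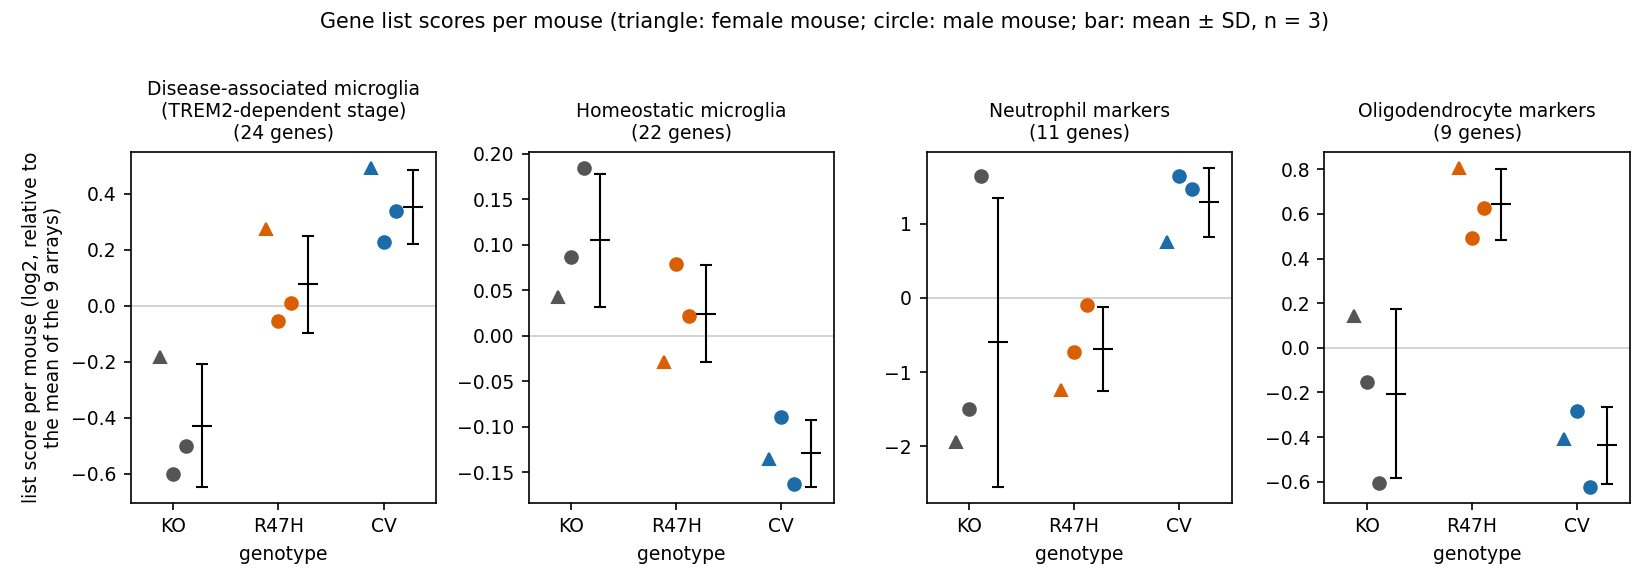
Score of each mouse for the TREM2-dependent DAM, homeostatic, neutrophil and oligodendrocyte lists, as the mean log2 deviation of the members from their means over 9 arrays. Triangles are females, circles males, and bars the mean ± SD of 3 mice, and KO mouse 3 lies at 1.63 on the neutrophil score while the other KO mice lie at -1.93 and -1.50.

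Between the sexes 7 genes were called, 5 higher and 2 lower in females (limma, Benjamini-Hochberg adjusted p under 0.05). Xist differed by 5.74 ± 0.12 (adjusted p = 7.27e-08), and the Y-linked Eif2s3y and Kdm5d by -4.57 ± 0.24 and -1.85 ± 0.10 (adjusted p = 0.000113 each). Eif2s3x, which escapes X inactivation, was higher in females by 0.68 ± 0.07 (adjusted p = 0.0194). Also higher were the endolysosomal protease gene Ctse by 0.79 ± 0.09 (adjusted p = 0.0194) and the selenoprotein gene Selenom by 0.68 ± 0.08 (adjusted p = 0.0384). The remaining called gene, Gm1673, chosen after its value was seen, stood at 0.57.

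The TREM2-dependent DAM list was higher in females, with 0 of 24 members over all genes and 14 when adjusted over the list alone (median 0.28, camera adjusted p = 6.01e-10, and adjusted p = 0.0402 with an estimated correlation). Igf1 stood at 0.54 ± 0.08 (limma adjusted p = 0.089), Itgax at 0.63 ± 0.13 and Cst7, a cystatin, at 0.36 ± 0.08. Lysosomal genes were higher too (2 of 29 adjusted over the list alone, median 0.11, adjusted p = 9.35e-06, and adjusted p = 0.0402 with an estimated correlation). The galactosylceramidase Galc stood at 0.47 ± 0.07 and the acid lipase Lipa at 0.29 ± 0.06. Lipid genes were higher (5 of 19 adjusted over the list alone, median 0.14, adjusted p = 0.000168, and adjusted p = 0.0676 with an estimated correlation), with Fabp3 at 0.60 ± 0.09. Higher in females were also the respiratory chain (median 0.10, adjusted p = 1.12e-05, Sdha at 0.25) and glycolysis (median 0.15, adjusted p = 0.00108, Pgk1 at 0.30). Members adjusted over the list alone numbered 0 and 4, and each list had adjusted p = 0.541 with an estimated correlation. Lists fixed as signs of RNA quality and of tissue dissociation moved with these female lists. Ribosomal protein genes, the sign of RNA quality, were higher in 20 of 20 (median 0.11, adjusted p = 9.78e-05, adjusted p = 0.541 with an estimated correlation, 0 adjusted over the list alone, Rpl19 at 0.18). Their mean of 0.10 was 0.05 with quantile normalization (adjusted p = 0.164) and 0.06 without KO mouse 1. Immediate early genes, the sign of dissociation, were lower in 23 of 24 (median -0.16, adjusted p = 8.4e-09, adjusted p = 0.541 with an estimated correlation, 0 adjusted over the list alone), with the heat shock gene Dnajb1 at -0.49 ± 0.12 and Klf2 at -0.25 ± 0.06. Their mean was -0.17, and -0.08 with the neutrophil score as a covariate (adjusted p = 0.00671). Neutrophil markers had a median of -1.29 (adjusted p = 9.78e-05, adjusted p = 0.581 with an estimated correlation, 0 adjusted over the list alone), with S100a8 at -1.83 ± 0.69. Their mean was -1.21, and -0.71 without KO mouse 3. Oligodendrocyte markers had a median of 0.25 (adjusted p = 0.00108, adjusted p = 0.581 with an estimated correlation, 1 adjusted over the list alone).

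Homeostatic (median -0.05, adjusted p = 0.00629), proliferation (median -0.06, adjusted p = 0.0285) and inflammatory genes (median -0.07, adjusted p = 0.0363) passed as lower in females. They had 0 members each adjusted over the list alone, and adjusted p = 0.581, 0.602 and 0.602 with an estimated correlation. The homeostatic and oligodendrocyte calls were lost without KO mouse 1 (adjusted p = 0.104 and 0.105), the proliferation call without KO mouse 2, R47H mouse 1 or R47H mouse 3 (up to 0.864). With the neutrophil score as a covariate the homeostatic mean went from -0.06 to -0.02 (adjusted p = 0.23), the oligodendrocyte mean from 0.27 to 0.09 (adjusted p = 0.311) and the inflammatory mean turned from -0.05 to 0.03 (adjusted p = 0.629). Without R47H mouse 1 the proliferation and inflammatory means turned to 0.01 and 0.02, from -0.08 and -0.05, and they lay at -0.15 without CV mouse 1 and -0.11 without KO mouse 1. The inflammatory call was lost without KO mouse 3, R47H mouse 1, R47H mouse 3, CV mouse 1 or CV mouse 3 (up to 0.528). Groups did not overlap for 3.69% of tested genes, where chance gives 2.38% for 3 mice against 6. Ctse lost its call without KO mouse 1, KO mouse 2, KO mouse 3, R47H mouse 1 or any CV mouse (adjusted p up to 0.268). Eif2s3x and Selenom lost theirs without any 1 of the 9 mice (adjusted p up to 0.167 and 0.379), while Xist, Eif2s3y and Kdm5d kept theirs. Each group's 1 female was also its mouse 1, so sex cannot be told apart from whatever else the number marks.

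With an estimated correlation, 4 camera calls held: the TREM2-dependent DAM list in CV minus KO, R47H minus KO and female minus male, and the lysosome list in female minus male. At the preset correlation 10, 9, 10 and 12 of 31 lists passed in CV minus KO, R47H minus KO, R47H minus CV and female minus male.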

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

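Chosen only after results were seen were the neuron marker test and the fits with a neutrophil score as a covariate or with every probe set under trend and robust options. Of 13767 probe sets outside the gene-level comparisons, because no single symbol was listed for them, 2 were called in CV minus KO by limma with trend and robust options, both higher in CV, the larger by 4.82 on the log2 scale. The same fit called 0 of them in R47H minus KO and 0 in R47H minus CV. Over all probe sets it gave 0 calls (1688 at an unadjusted p under 0.05) and 5 calls there. Their genes were not named here.

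Neutrophil markers lay higher in CV than in KO by a median of 2.03, and in KO mouse 3 (score 1.63) about as high as in the CV mice (0.76 to 1.64). The CD45+ CD11b+ gate keeps neutrophils and monocytes, and their presence in the sort is a candidate explanation, as the markers deviated together between mice of one genotype with a median pairwise correlation of 0.932, against 0.176 at the 95th percentile of 1000 random lists. S100a8 and S100a9 reached 12.61 and 12.34 in CV, 5 of the 11 were at or above the filter in every array, and 0 belong to another list. The DAM list of microglial genes deviated together too (0.478 against 0.157), but these deviations still held sex, by which that list differed. With sex in the model, camera's estimated correlation was 0.02 for the DAM list, 0.82 for neutrophil markers and 0.87 for the interferon list. The interferon list is a pathway and not a cell type, so moving together does not single out another cell type. KO mouse 3, which carried the signal without human TREM2, is a single mouse that excludes no explanation. Whether human TREM2 changes how many such cells enter the brain, or blood left after perfusion differed between mice, stays open and was not tested.

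Oligodendrocyte markers lay higher in R47H than in KO by a median of 0.68 and higher than in CV by 1.14, although the gate would remove oligodendrocytes. RNA carried over into the sorted cells, or myelin taken up by microglia, may be the source. The markers deviated together within genotypes, with a median pairwise correlation of 0.733 against 0.172 at the 95th percentile of random lists. So did the microglial DAM list (0.478 against 0.157), in deviations that still held sex. With sex in the model, camera's estimated correlation was 0.61 for these markers, 0.02 for the DAM list and 0.87 for the interferon list. As the interferon list is a pathway, moving together does not single out another cell type. Of the 9 markers 7 were at or above the filter in every array, with Trf at 11.51 and Mbp at 8.21 in R47H and 0 held by another list. Astrocyte markers (S100b 7.86 in R47H, 2 of 6 at or above the filter in every array, 1, Clu, in another list) were higher in R47H as well, with a within-genotype correlation of 0.328 against 0.290. A general carry-over of brain RNA could not be decided, because neuron markers had a median difference of -0.0104 at a median level of 4.50, under the filter of 5.31, and a change in R47H microglia themselves stays open.

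The TREM2-dependent DAM list lay highest in CV, lower in R47H and lowest in KO. Whether neutrophils in the gate are the whole cause could not be decided. With the neutrophil score as a covariate 95.6% of the list's CV minus KO difference remained (0.75, camera adjusted p = 2.57e-15, over all alternatives up to 0.0172). Between CV and R47H 87.0% of the difference remained (adjusted p = 0.0279, over all alternatives up to 0.234). KO mouse 3 had the DAM score of a KO mouse (-0.50, others -0.18 and -0.60) despite its neutrophil score. The covariate fit rests largely on the same mouse, as the neutrophil score had an SD of 1.95 in KO against 0.57 in R47H and 0.47 in CV. Both observations therefore rest largely on 1 mouse. In each genotype mouse 1 had the lowest neutrophil score and the highest DAM score (KO -1.93 and -0.18, R47H -1.24 and 0.27, CV 0.76 and 0.49). That is the opposite of neutrophils raising the list, but mouse 1 was the female in each group. It cannot be told apart from a sex difference and does not decide the question. A dependence on TREM2 variant is a hypothesis that stays open, and so do monocytes, whose score was not used as a covariate, and the amount or activity of each human transgene, which was not measured here.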

How the results depend on the processing

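Chosen only after results were seen were the fits with a neutrophil or oligodendrocyte score, the share within mouse number and the fit of every probe set with trend and robust options. The DAM list in CV minus KO and R47H minus KO kept its direction and an adjusted p under 0.05 in all alternatives run. Its score kept an exact permutation p under 0.05 before adjustment (0.00714 to 0.0214). After adjustment over all lists the score did not pass in any of them (adjusted p = 0.0554 to 0.166). The R47H share, to which no threshold applies, ran from 51.9% to 73.3%. Set against the KO and CV means, the shares of the 3 R47H mice had an SD of 22.4%, and within mouse number, which also holds sex, the share was 67.5%, 65.7% and 61.0% (mean 64.7%, SD 3.35%). The numbers are not stated to pair mice. The smaller SD therefore holds for a single matching of the males and does not measure precision. In R47H minus CV the DAM list lost its call with an estimated correlation (adjusted p = 0.234) and with fry (0.0589) and kept it otherwise. Without each mouse in turn its mean was 0.74 to 0.82 in CV minus KO, 0.46 to 0.54 in R47H minus KO and -0.32 to -0.23 in R47H minus CV. The cause of the changes given here was not tested, apart from fewer samples, fewer degrees of freedom or more tests, which the settings themselves impose.

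Calls by limma numbered 131, 9, 86 and 7 in CV minus KO, R47H minus KO, R47H minus CV and female minus male, and 142 for any genotype difference. Without sex they were 77 and 3 in CV minus KO and R47H minus KO, and 85 for any genotype difference, and with sex alone and no genotype 3 in female minus male. With every probe set tested, which lowers the prior degrees of freedom from 3.73 to 1.94, the 3 genotype comparisons and the F-test gave 18, 0, 5 and 17. With trend and robust options added they were 17, 0, 5 and 14, where the 0 in R47H minus KO came with 1743 and 1688 at an unadjusted p under 0.05. The neutrophil score gave 23, 15, 9, 3 and 37, the oligodendrocyte score 0 in R47H minus KO (446 at an unadjusted p under 0.05) and 0 in R47H minus CV (371), a score that itself follows genotype. The compared groups alone gave 54 in CV minus KO and 1 in R47H minus KO. Trend and robust options gave 15 in R47H minus KO, array weights 15 in female minus male, and no filter 48 in R47H minus CV. An absolute difference of at least 1 left 37, 4, 40 and 3, and an adjusted p under 0.10 gave 234, 31, 140 and 16. Quantile normalization, median centring and the stricter filter moved no count by over 1.5 times. Without each mouse in turn the counts were 59 to 172, 0 to 7, 9 to 132, 3 to 5 and 35 to 163. In CV minus KO the neutrophil score left the median size of the 131 differences at 0.73 from 0.76 while their median SE rose from 0.107 to 0.141, and in R47H minus CV at 0.78 from 0.92 (SE 0.125 to 0.157). With the oligodendrocyte score the 8 tested genes of R47H minus KO kept their directions at 0.81 from 0.90 (SE 0.099 to 0.239), and 72 of 81 of R47H minus CV did, at 0.54 from 0.88 (SE 0.1197 to 0.308).

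Lists passing numbered 10, 9, 10 and 12, with an estimated correlation 1, 1, 0 and 2, and with fry 4, 1, 3 and 4. No filter gave 14 in R47H minus KO, the neutrophil score 5 in CV minus KO and 6 in R47H minus CV, and leaving out 1 mouse 4 to 13 in R47H minus KO. Signs of list means turned with the neutrophil score for immediate early genes in CV minus KO (-0.0187) and R47H minus CV (0.0567) and for oligodendrocyte markers in CV minus KO (0.0455). They also turned with it for inflammatory genes in R47H minus CV (0.0315) and female minus male (0.0274). They turned for neutrophil markers in R47H minus KO without KO mouse 3 (-0.80 to 0.91 over single removals), and for interferon genes without R47H mouse 3 (-0.049 to 0.55). Without R47H mouse 1 they turned in female minus male for proliferation (-0.152 to 0.0124 over single removals) and inflammatory genes (-0.113 to 0.0167). With the oligodendrocyte score R47H minus CV turned for Apod (-0.30), Cmtm5 (-0.14), Car2 (-0.20), Cryab (-0.15) and Gpm6b (-0.20). Each had a limma adjusted p of 0.999919 there, so these signs are uncertain. Of 27, 8, 32 and 6 named genes called, 18, 0, 4 and 3 kept their calls without any 1 mouse.

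The mouse numbers are not stated to pair mice. On a measure other than the raw correlations between arrays, same-number pairs correlated at -0.04 to 0.36, 7 of 9 above 0.1. For 5 of 9 arrays the closest array of another genotype had its number. The pairs of mouse 1, the female of each group, had the highest values (0.32 to 0.36), so sex may contribute to them. With the number as a block in place of sex, limma called 136, 11 and 83 genes and 136 for any genotype difference. These held 113 of the 131, all 9 and 70 of the 86 calls. The differences themselves cannot change in this fit, because every genotype holds the same mouse numbers. Of the named genes Gramd1b and Rapsn lost their calls in CV minus KO, and Cmtm5, Cldn11, Mid1, Adgre5, Lgals3 and Mlph in R47H minus CV (adjusted p from 0.0521 to 0.067). Cxcl16 in CV minus KO and Ch25h in R47H minus KO gained one, and of list calls the lipid list in CV minus KO was lost (adjusted p = 0.0599) and 2 in R47H minus KO were gained. No block fit was possible for sex, nor a fit of the compared groups alone for sex and the F-test. Low signal limits genes near or under the filter of 5.31, whose folds may be compressed.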

Other observations

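The fit with the neutrophil score was the only test of this part chosen after the results were seen. Border-associated macrophages, which line brain vessels and meninges, share the CD45+ CD11b+ gate, and all 11 of their tested markers were at or above the filter in every array. In R47H minus CV 10 of 11 were positive, and 1 was called over all genes and adjusted over the list alone, the scavenger receptor Cd163 (0.56 ± 0.08, limma adjusted p = 0.0235). The list passed (median 0.25, camera adjusted p = 0.00159, and adjusted p = 0.263 with an estimated correlation). The call for Cd163 was lost without any R47H mouse, CV mouse 1 or CV mouse 3 (adjusted p up to 0.152), and with the neutrophil score as a covariate the list no longer passed, its mean at 0.13 against 0.26 (adjusted p = 0.401, the highest over its alternatives). In CV minus KO the list did not pass (adjusted p = 0.164), with Ms4a7 higher at 0.82 ± 0.15 (adjusted p = 0.0423, lost without any 1 mouse except KO mouse 3, and 0.51 with the neutrophil score) and Cbr2 at -0.75 (adjusted p = 0.0935). Among other markers, the endothelial Flt1 was higher in CV than in KO (1.55 ± 0.17, adjusted p = 0.00413) while its list was not (adjusted p = 0.641).

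Orthologues of Alzheimer risk genes showed 0 of 23 calls in any comparison, over all genes (limma) or adjusted over the list alone, with 7, 2 and 5 at an unadjusted p under 0.05 in CV minus KO, R47H minus KO and R47H minus CV. As a list they did not pass (camera adjusted p = 0.382, 0.34 and 0.778 in the same order). Apoe, the lipid carrier, stood at 0.19 and Inpp5d, a phosphatase downstream of TREM2, at -0.18 in CV minus KO. The TREM2-independent stage of DAM likewise had 0 calls among 7 members (limma, 2 and 0 at an unadjusted p under 0.05, median 0.07 in CV minus KO and 0.08 in R47H minus KO, adjusted p = 0.144 and 0.111), although the TREM2-dependent stage rose in both. Receptor complex genes (15 tested, median -0.01 in CV minus KO, adjusted p = 0.962) and autophagy genes (median 0.01, adjusted p = 0.476) did not pass. Complement and Fc receptor genes (median -0.03, adjusted p = 0.454, Itgam at -0.30) and apoptosis genes (median 0.11, adjusted p = 0.0987) missed as well. These misses do not show that the genes were equal.

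Sex by genotype interactions gave 0 genes in each of the 3 genotype comparisons (limma, 434, 418 and 329 at an unadjusted p under 0.05), and no list passed, with 1 female per group. Other groupings of the same arrays tested whether chance could give as many calls. Among 100 drawn from the 270 arrangements of 9 arrays into 3 groups that the model can fit, 1, the real one, reached 142 genes with any genotype difference, and the highest other gave 38. The other arrangements were not required to balance sex as the real one does. The share therefore speaks against chance assignment without excluding it. Among the 81 splits into 3 and 6 arrays that it can fit 1, the real one, reached 7 genes, and the highest other gave 1. For 3 mice against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 that reached its count in CV minus KO (131, highest other 0), R47H minus KO (9, highest other 1) and R47H minus CV (86, highest other 0).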
